A study of Homo sapiens with 5 samples.

How the data were processed

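Ribosome-protected fragments were counted per gene in 5 libraries of HCT116 cells, 2 labelled wild type (WT) and 3 labelled eIF6 mutant (MUT). Per the labels' protocols, cells were grown to 60 to 70% density and their extract was digested with MNase and DNase. The extract was then separated on a sucrose gradient and RNA was taken from the fraction holding single 80S ribosomes. Fragments of 25 to 35 nucleotides were cut from a gel, depleted of rRNA and made into small-RNA libraries. MNase cuts preferentially next to A and T, so the footprints recovered depend on base composition.

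The deposited values are raw counts, whole numbers not normalized by the authors, for 17297 genes per library, and no row stood for unassigned reads. Per the submitters' processing notes, cutadapt 4.6, FastQC 0.12.1, STAR 2.5.2b, DESeq2 1.42.0 and the build hg38 were used. The counting tool, the annotation, the counted part of each gene, the treatment of reads that map to several places and any use of strand are not given in the sources used here. Genes that share sequence with near-identical copies or overlap other genes are therefore uncertain. Libraries were matched to samples by the sample codes in the table's header, and a sheet that repeats sample labels was not used. RNA-seq libraries were not analysed here. Gene names were matched to NCBI's table for GRCh38.p14, which has the same chromosomes as hg38. Of the names, 17253 matched and 44 did not, and those 44 were still tested.

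Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), libraries were scaled by TMM (factors from 0.959 to 1.03), and the quasi-likelihood F test compared MUT with WT over all 5 libraries with 3 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Log2 fold changes are MUT over WT. Their standard errors were computed from the F statistic. CPM values (computed by edgeR from the TMM-scaled library sizes) are given as mean ± SD over 2 WT and 3 MUT libraries. The common biological coefficient of variation was 7.37%.

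Library totals ran from 2095217 to 3821176 counts, with the smallest in WT replicate 1. All 10 pairs of libraries differed by more than counting error (chi-square per gene from 1.9 to 8.01), so no library was counted as a copy of another. The share of counts in a gene class was compared with an exact two-sided permutation test over the 10 splits of the libraries, whose smallest p is 0.1. For a single library the 95% exact binomial interval of such a share was narrow (0.957% to 0.984% for mitochondrially encoded genes in WT replicate 1). It covers counting error only, since molecular identifiers are not mentioned in the sources used here.

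Before the data were examined, 40 gene lists were fixed. They covered ribosomal proteins, other TOP mRNAs, translation initiation, ribosome assembly, RNA polymerases I and III, mitosis and replication, histones, p53 targets, stress responses and chaperones, the proteasome, glycolysis, lipid synthesis, respiration, MYC, WNT and MAPK signalling, epithelial and mesenchymal genes, interferon, NF-kB, hypoxia, lysosome, redox and ribosome quality control genes, and markers of other cell types. The table held 97.5% of the listed genes. Lists with at least 5 tested genes were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 38 lists.

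The named genes were also fixed by rule. They are EIF6, then the 8 largest rises and 8 largest falls past the threshold with a mean of at least 10 CPM and all MUT libraries on one side of all WT libraries. Next come the 4 most abundant such rises and falls, and up to 4 genes with the lowest p in each list described, with at most 2 where none passed. Some genes, among them genes under this rule, are not reported here. Genes outside this rule are said to be named after their values were seen.

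The test was checked on simulated counts drawn from the real genes' means and library sizes, with 200 of 11966 genes changed. For this comparison it recovered 18% of genes changed 1.25-fold, 56% at 1.5-fold, 84% at 2-fold and 94% at 3-fold, with 50 genes of each size. Of 136 calls 10 were false, and 0 calls were made with no change simulated. Changes under 1.5-fold were therefore often missed in this simulation. In the real data 22.9% of tested genes were called, which loosens the cutoff on the unadjusted p, so these rates need not hold there. Of 30 simulated lists of 40 genes, both lists shifted by 0.3 log2 were called and 0 of the rest. Simulated genes were drawn independently of each other, so this check does not cover correlation between the genes of a list.

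Alternatives fixed in advance were RLE and upper-quartile scaling, library size only, DESeq2 1.42.0, limma-voom, robust dispersion, no count filter and a strict one (30 counts in at least 2 libraries and a mean of 10 CPM). The replicate number as a block, each library left out, gene classes left out, a 2-fold and a looser threshold (0.1), camera with an estimated correlation, fry, and another denominator for shares completed that set. Alternatives added after seeing the data were removing a trend with gene density and gene span, thinning all libraries to the smallest total, and leaving out Y-linked genes. No genome sequence was used, so gene density (protein-coding genes within 1 Mb on each side) and gene span stood in for base composition, fitted as splines with 4 degrees of freedom per library. Figures were drawn with matplotlib 3.10.9.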

Results

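Ribosome profiling sequences the mRNA fragments that ribosomes shield from nuclease, so a gene's count reflects how many ribosomes were on its mRNAs. Libraries were scaled to each other here, so rises and falls are relative to the other genes. A change common to all genes would not be seen. It was measured here in HCT116, a human colorectal carcinoma cell line. The WT group was unedited cells with 2 libraries. The MUT group, with 3 libraries, was cells made homozygous by CRISPR/Cas9 editing for an asparagine-to-serine change in eIF6. eIF6 is a factor that binds the large (60S) ribosomal subunit, takes part in its assembly and keeps it from joining the small (40S) subunit. By its title, the series asks what targeting eIF6 does to ribosomal subunits, to the exit from mitosis and to cancer growth. RNA-seq libraries that the design text mentions were not analysed here, so a change in footprints is not split into a change in mRNA and a change in ribosomes per mRNA.

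The libraries held 2095217 and 3128144 counts in WT replicates 1 and 2, and 3076137, 3755991 and 3821176 in MUT replicates 1, 2 and 3. Across genes, which are not independent replicates, log2 CPM correlated at Pearson's r = 0.9795 between the WT libraries, at 0.9823 to 0.985 between MUT libraries and at 0.96 to 0.9672 across the groups. The first principal component, with 55.6% of the variance, placed both WT libraries at negative values and the 3 MUT libraries at positive ones. The labels do not say whether libraries of a group came from separate cultures or clones. The p-values therefore measure only the spread between these libraries, which may be technical, and an effect of the mutation is not separated from other differences between the edited and unedited cells.

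The largest rise under the naming rule was on CPA4, a secreted carboxypeptidase, which went from 15.9 ± 0.612 CPM in WT (SD, n = 2) to 81.2 ± 9.66 CPM in MUT (SD, n = 3), 5.06-fold. The transcription factor RUNX2 rose 3.65-fold, the protein cross-linking enzyme TGM2 3.54-fold and the matrix glycoprotein THBS1 3.15-fold. On the falling side, the adhesion protein PCDH7 went from 276 ± 6.45 to 16.3 ± 2.63 CPM, 17-fold lower, and VASP, which promotes actin filament growth, was 6.14-fold lower. RPS4Y1, the Y-linked copy of a ribosomal protein gene, had 151 and 289 counts in WT and 4, 5 and 0 in MUT, 98.5-fold lower.

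Of 11991 genes tested with edgeR's quasi-likelihood test, 1203 were higher and 1544 lower in MUT at an adjusted p under 0.05, and 9244 did not pass. At an unadjusted p under 0.05 there were 4295. Changes were mostly small: the median called gene was 1.47-fold higher or 1.37-fold lower, and 144 higher and 81 lower genes changed at least 2-fold. All libraries of one group lay on the same side of all libraries of the other for 50.7% of tested genes, where chance gives 20%. The share of calls that were higher, 43.8%, was 56.3% with upper-quartile scaling and 62.8% with library size only, so these counts do not settle whether more genes rose or fell. DESeq2 called 609 higher and 948 lower genes, and without WT replicate 2 edgeR called 509 and 732. Without WT replicate 1 the higher genes numbered 646, and without MUT replicate 1 the calls were 721 higher and 908 lower.

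EIF6 itself (gene ID 3692, chromosome 20, 35278906 to 35284772 on GRCh38.p14) had 178 ± 9.16 CPM in WT (SD, n = 2) and 157 ± 10.7 CPM in MUT (SD, n = 3). Its log2 fold change of -0.17 (SE 0.0971) did not pass, with edgeR's adjusted p at 0.215. A change of 1 amino acid need not alter a gene's footprint count, so this value does not check the labels.

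The other genes with the largest rises were TMEM158 with a log2 fold change of 1.70, VEPH1 with 1.59, and CLPTM1 and HECW1 with 1.56 each. The other large falls were ADGRF1 and KRT23, an adhesion receptor and a keratin, with log2 fold changes of -2.15 each. MAL2, a protein of apical transport in epithelia, followed with -1.93, the transcription factor NFIB with -1.80 and the neuronal calcium sensor VSNL1 with -1.65. Adjusted p for these 16 genes lay at or below 0.000748 (HECW1), and each stayed past the threshold in all alternative fits that tested it. RPS4Y1 was not in the fit without Y-linked genes. CPA4 lies on chromosome 7 at 130293161 to 130324180, PCDH7 on chromosome 4 at 30720369 to 31146800 and VASP on chromosome 19 at 45507479 to 45526983 (GRCh38.p14 gene bounds).

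**Figure D1:**
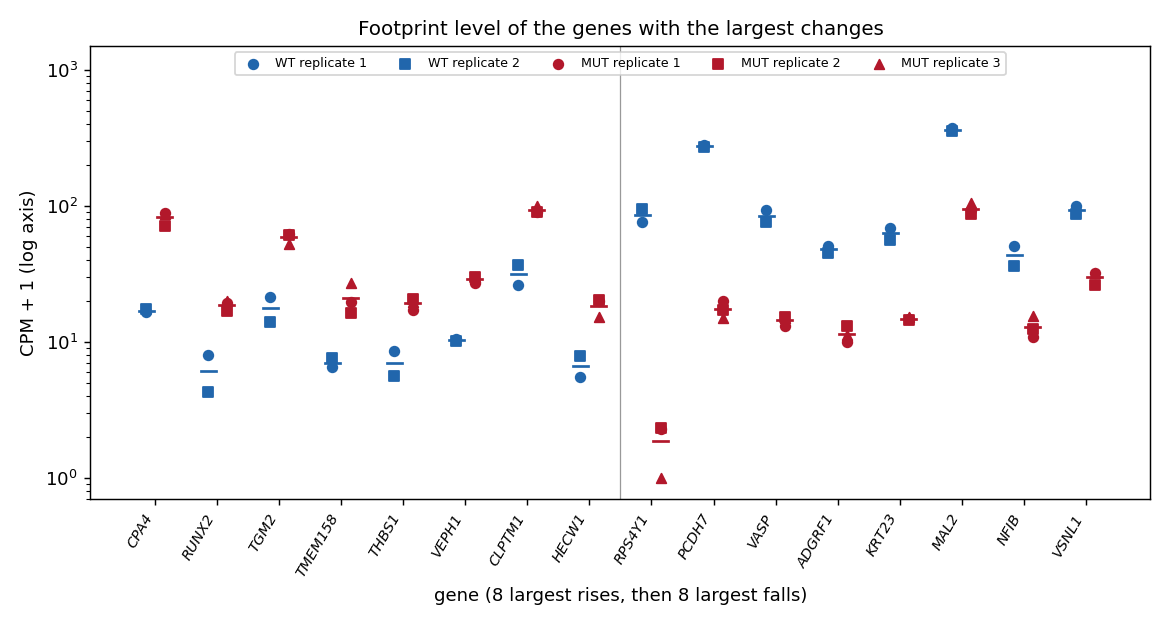
CPM + 1 on a log axis for the 8 largest rises and the 8 largest falls, with 1 point per library (blue for WT, red for MUT) and a horizontal bar at each group mean. WT and MUT points do not overlap for any of these 16 genes, as the naming rule required, and RPS4Y1 has a library at 0 CPM in MUT.

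Among abundant genes, the cell cycle regulator CCND1 (cyclin D1) rose from 637 ± 21 to 988 ± 37.3 CPM, and the pyruvate dehydrogenase phosphatase PDP1 fell from 1611 ± 136 to 1183 ± 65.5 CPM. Their adjusted p values in edgeR were 7.14e-05 and 0.0027. The other abundant genes changed less. The membrane-actin linker EZR (1.35-fold) and the RNA-binding HDLBP (1.28-fold) were higher. ITPRID2, the poly(A)-binding PABPC1 and the mitochondrially encoded COX2 were lower, with log2 fold changes of -0.32, -0.34 and -0.37. These 5 calls ended when single libraries were left out, for example EZR and HDLBP without WT replicate 2 (adjusted p 0.0511 and 0.13), and PABPC1, ITPRID2 and COX2 without WT replicate 1 (0.263, 0.106 and 0.36). ITPRID2 and PABPC1 also lost their calls with upper-quartile scaling (0.0571 and 0.056), with library size only (0.0552 and 0.0559) and with the trend of gene density and span removed. In that last fit their log2 fold changes were -0.15 and -0.22 (0.298 and 0.154).

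Footprints on mRNAs of ribosomal proteins fell. Of 47 large-subunit protein genes tested, 27 fell and 0 rose, or 33 and 0 adjusted over the list alone, and the list's median log2 fold change was -0.35. The test of the list against other genes (camera) gave an adjusted p of 8.1e-11, and an adjusted p = 0.666 with an estimated correlation. RPL23A went from 159 ± 3.91 to 93.9 ± 9.59 CPM and RPL39 from 222 ± 4.37 to 145 ± 7.85 CPM. Of 33 small-subunit protein genes 15 fell and 0 rose, or 16 and 0 adjusted over the list alone, with a median of -0.25. Camera gave an adjusted p of 1.23e-05, and adjusted p = 0.674 with an estimated correlation. RPS3A was 1.56-fold and RPS7 1.59-fold lower. Other mRNAs with a 5′ terminal oligopyrimidine (TOP) start, the motif that ribosomal protein mRNAs share, moved the same way: 14 of 22 fell and 0 rose, or 16 and 1 adjusted over the list alone. Their median was -0.34 and the camera adjusted p 1.3e-05, with adjusted p = 0.503 with an estimated correlation. NAP1L1, a histone chaperone, was 1.5-fold lower and HNRNPA1, a splicing regulator, 1.38-fold lower.

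The WT libraries differed from each other in these groups. Large-subunit protein genes stood on average 0.33 log2 units above their mean over the libraries in WT replicate 1 and 0.06 in WT replicate 2, against -0.09, -0.13 and -0.18 in the MUT libraries. Without WT replicate 1, 11 large-subunit genes fell and 1 rose (median -0.22) and 7 TOP genes fell, with both lists still called, while 5 small-subunit genes fell and that list lost its call (median -0.12, adjusted p 0.0514). The small-subunit median was -0.41 without WT replicate 2. Without MUT replicate 1, 8 small-subunit and 9 TOP genes fell, and 9 TOP genes fell with library size only or with the trend of gene density and span removed. Ribosomal protein genes held 3.18% ± 0.43 of all counts in WT (SD, n = 2) and 2.71% ± 0.0949 in MUT (SD, n = 3). The exact two-sided permutation test gave p = 0.1, the smallest that groups of 2 and 3 can give. That difference of -0.472 percentage points was -0.168 without WT replicate 1 and -0.776 without WT replicate 2. Many ribosomal protein genes have near-identical pseudogene copies, and how the deposited counting treated reads that map to several places is not given in the sources used here, so single values of these genes are uncertain.

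Genes of ribosome assembly rose. For the small subunit (40S), 19 of 45 rose and 1 (FBL, the rRNA methyltransferase fibrillarin, named after its value was seen) fell, or 23 and 1 adjusted over the list alone, with a median of 0.24. For the list, camera's adjusted p was 3.56e-05, and adjusted p = 0.596 with an estimated correlation. DHX37 went from 26.5 ± 2.81 to 54.4 ± 3.30 CPM, and NOL6 and RRP12 rose 1.89-fold and 2.15-fold. For the large subunit (60S), 17 of 46 rose and 2 fell, or 19 and 5 adjusted over the list alone, with a median of 0.10. The camera adjusted p was 0.00686, and adjusted p = 0.674 with an estimated correlation. NOC2L rose 1.78-fold and FTSJ3 1.81-fold. RSL24D1 and NSA2, which fell, were named after their values were seen. Without WT replicate 1 the 60S list had a median of 0.05 and lost its call (adjusted p 0.056), and 12 of the 40S genes rose (median 0.16). The 60S median ranged up to 0.19 (without WT replicate 2) in the other fits. Without WT replicate 2, 10 genes of each list rose. Genes of RNA polymerases I and III, which transcribe rRNA and tRNA, included 10 that rose and 3 that fell among 33, before and after adjustment over the list alone, and the list missed the threshold (adjusted p 0.0511). It passed with upper-quartile scaling (0.0308), for example, and not without WT replicate 1 (0.14), where 2 of its genes rose. The number that rose was 5 without WT replicate 2 and 3 without MUT replicate 2. GTF3C1 and POLR3D rose and TAF1D fell, where GTF3C1 lost its call without WT replicate 1 (0.129) and POLR3D without WT replicate 1 (0.0629) or WT replicate 2 (0.0519). Of 30 translation initiation factors 4 rose and 7 fell, also adjusted over the list alone (camera adjusted p 0.652). The number that fell was 4 without WT replicate 1, 3 without WT replicate 2 and 2 without MUT replicate 1. With upper-quartile scaling 5 rose and 5 fell, and with library size only 7 rose and 5 fell. EIF4G1, the scaffold of the cap-binding complex, rose 1.59-fold and EIF4A2, a helicase of that complex, fell 1.54-fold.

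Mitosis genes fell at the kinetochore. Of 37 genes of the spindle assembly checkpoint and kinetochore, which hold chromosomes to the spindle and delay anaphase, 17 fell and 0 rose, or 20 and 1 adjusted over the list alone. The median was -0.30 and the camera adjusted p 3.56e-05, with adjusted p = 0.503 with an estimated correlation. With the trend of gene density and span removed the median was -0.20. CENPF went from 675 ± 112 to 401 ± 32.1 CPM, SPC25 fell 1.63-fold, and the checkpoint protein MAD2L1 and checkpoint kinase TTK fell 1.41-fold and 1.4-fold. Without WT replicate 2 the falling genes numbered 7 (list median -0.18), and without MUT replicate 1 or with library size only they numbered 11, with the list still called in these fits.

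The list closest to the series' title, the anaphase-promoting complex and mitotic exit, was not called. Of its 42 genes 12 fell and 3 rose, also adjusted over the list alone, with a median of -0.12 and a camera adjusted p of 0.0817. The lowest p belonged to SKP1, a subunit of another ubiquitin ligase (SCF), which fell with a log2 fold change of -0.51. CDK1 (1.43-fold lower) and CCNB2 (1.41-fold lower), the kinase and a cyclin whose inactivation ends mitosis, and the phosphatase subunit PPP1CB fell too. Of the list's genes 6 fell and 0 rose without WT replicate 2 and with the trend of gene density and span removed, and 7 fell and 0 rose without MUT replicate 1. The 3 that rose, named after their values were seen, were the complex's subunits ANAPC2 and ANAPC11 and the phosphatase subunit PPP2R5D, and 1 rose without WT replicate 1, without MUT replicate 2 or with all libraries thinned to the smallest. CCNB2 lost its call without WT replicate 2 (adjusted p 0.0977). Of 35 genes of the spindle, passenger complex and cytokinesis 9 fell and 0 rose, or 9 and 3 adjusted over the list alone (camera adjusted p 0.0817). KIF18A, a kinesin that limits microtubule length, fell 1.56-fold. That list was called without WT replicate 1 (0.0042) and MUT replicate 2 (0.00769), and had an adjusted p of 0.54 without WT replicate 2, where 1 gene fell. Without MUT replicate 1, 3 fell. With other scalings 4 rose and 7 fell (upper quartile) or 4 rose and 5 fell (library size only), and with the replicate block 4 rose and 10 fell.

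Histones and replication genes were mixed in size. Of 50 replication-dependent histone genes 12 fell and 0 rose, or 14 and 0 adjusted over the list alone, with a median of -0.19. Camera gave an adjusted p of 0.000248, and adjusted p = 0.674 with an estimated correlation. H4C8 fell 1.74-fold and H2BC4 1.47-fold, although near-identical histone genes make single values uncertain. The number that fell was 6 without WT replicate 1 or MUT replicate 1, and 5 without MUT replicate 3. It was also 6 with upper-quartile scaling and with library size only, and 5 with the trend of gene density and span removed. The list's median was -0.12 without WT replicate 1 and with library size only, and -0.11 without MUT replicate 3 and with the replicate block. Histones held 1.64% ± 0.156 of counts in WT (SD, n = 2) and 1.47% ± 0.0976 in MUT (SD, n = 3), with an exact permutation p of 0.3. That difference of -0.17 points was -0.0591 without WT replicate 1 and -0.28 without WT replicate 2. Among 58 genes of the G1/S transition and DNA replication 3 rose and 10 fell, or 3 and 13 adjusted over the list alone (camera adjusted p 0.117). Camera called that list without WT replicate 1 (0.0259) and without MUT replicate 2 (0.0229). The replicative helicase subunit MCM2 rose 1.6-fold and the replication inhibitor GMNN fell 1.55-fold. Among 24 genes of condensin, cohesin and topoisomerase 2 rose and 5 fell, also adjusted over the list alone (camera adjusted p 0.351), with the cohesin subunit RAD21 at a log2 fold change of -0.54. Of these, 1 fell without WT replicate 2 and 3 without MUT replicate 1 or MUT replicate 3.

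Respiratory chain genes fell in both genomes. Of 77 nuclear-encoded oxidative phosphorylation genes 33 fell and 1 rose (NDUFS7, named after its value was seen), or 38 and 1 adjusted over the list alone, with a median of -0.24. The camera adjusted p was 2.6e-08, and adjusted p = 0.503 with an estimated correlation. NDUFB6, of complex I, went from 190 ± 3.28 to 104 ± 17.2 CPM, and COX7B, of complex IV, fell 1.62-fold. Without WT replicate 2, 15 fell and the list stayed called. Of the 13 protein-coding genes of the mitochondrial genome, 8 fell and 1 rose (ND3, named after its value was seen). Adjusted over the list alone the counts were 11 and 1, and the median was -0.40. This list's camera adjusted p was 5.17e-06, and adjusted p = 0.503 with an estimated correlation. COX1, the mitochondrially encoded oxidase subunit, went from 1763 ± 285 to 1053 ± 21.8 CPM, and ND4L and ND4 fell 1.57-fold and 1.5-fold. The 13 genes held 0.88% ± 0.128 of counts in WT (SD, n = 2) and 0.661% ± 0.0117 in MUT (SD, n = 3), with an exact permutation p of 0.1. WT replicate 1 had 0.97% and WT replicate 2 had 0.789%, and the difference of -0.219 points was -0.128 without WT replicate 1. Whether these footprints came from mitochondrial ribosomes, which sediment differently from the 80S fraction collected, is not given in the sources used here. Among 69 mitochondrial ribosomal protein genes 1 rose and 9 fell, or 0 and 4 adjusted over the list alone (camera adjusted p 0.144), with MRPS33 and MRPS6 at -0.61 and -0.60. The number that fell was 2 without WT replicate 2 and 4 without MUT replicate 1, and other scalings gave 2 rises and 5 falls (upper quartile) or 4 and 4 (library size only).

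Lipid synthesis genes fell in part. Of 24 cholesterol synthesis genes 7 fell and 1 rose, also adjusted over the list alone, with a median of -0.23. Camera's adjusted p was 0.0342, and adjusted p = 0.503 with an estimated correlation. STARD4, a sterol carrier, fell 1.66-fold, the isoprenoid enzyme IDI1 1.52-fold and INSIG1, the sterol-sensing regulator, 1.8-fold. This list lost its call without WT replicate 2 (adjusted p 0.0612), where 4 genes fell and the median was -0.13. Of 24 genes of fatty acid synthesis 4 fell and 1 rose, also adjusted over the list alone (camera adjusted p 0.345). The desaturase SCD fell from 413 ± 5.07 to 243 ± 9.85 CPM, and ACSL3 and ELOVL6 fell too.

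The list of p53 targets rose. Of 32 genes tested 11 rose and 2 fell, also adjusted over the list alone, with a median of 0.26. The camera adjusted p was 1.56e-05, and adjusted p = 0.503 with an estimated correlation. The kinase PLK2 went from 129 ± 5.97 to 257 ± 10.7 CPM, and the cell cycle inhibitor CDKN1A (p21) from 321 ± 46.6 to 574 ± 49.1 CPM. CCNG1 was 1.44-fold lower. The number that rose was 6 without WT replicate 2, and the list stayed called.

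Mesenchymal and invasion genes rose in small number. Of 21 tested 5 rose and 0 fell, or 6 and 0 adjusted over the list alone, with a median of 0.36. The camera adjusted p was 0.0164, and adjusted p = 0.503 with an estimated correlation. The receptor kinase AXL went from 31.5 ± 4.84 to 63.4 ± 4.07 CPM, the repressor ZEB1 rose 1.91-fold, and SNAI2, at 0.913 ± 0.828 CPM in WT, had 4.44 ± 1.36 CPM in MUT. Without WT replicate 2 the list lost its call (adjusted p 0.0612), as did ZEB1 and SNAI2 (0.109 and 0.289), and 2 genes rose. Epithelial junction and keratin genes went both ways, with 6 of 33 higher and 8 lower, or 7 and 8 adjusted over the list alone (camera adjusted p 0.636). The list's median was 0.04 and its mean -0.05, with the test's direction down. The counts were 2 higher and 2 lower without WT replicate 2, and the higher genes numbered 3 without WT replicate 1 and 2 without MUT replicate 1 or MUT replicate 2. Besides KRT23, the epithelial transcription factor GRHL2 and the splicing factor ESRP1 fell, with log2 fold changes of -0.97 and -0.56, and the hemidesmosome integrin ITGB4 rose 1.91-fold. GRHL2 lost its call without WT replicate 2 (0.0548). Of 15 WNT targets and colon stem cell markers 3 rose (CCND1, DKK1 and SOX9) and 0 fell, or 3 and 1 adjusted over the list alone (camera adjusted p 0.187). The median of that list was -0.02, its mean 0.13 and the test's direction up. SOX9 lost its call without WT replicate 2 (0.087), where 2 genes of the list rose and 1 fell. The list was called with the trend of gene density and span removed (0.0369).

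**Figure D2:**
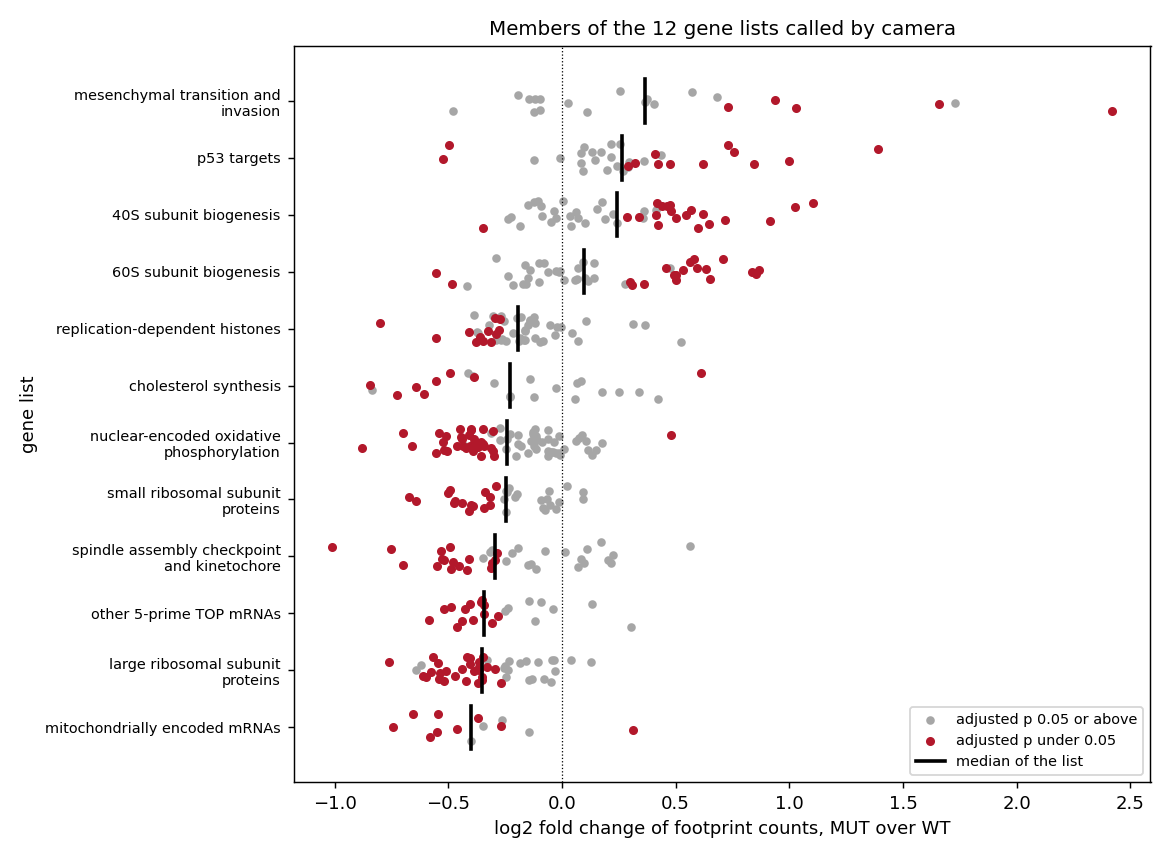
Log2 fold change of footprint counts (MUT over WT) of each tested member of the 12 gene lists called by camera with a preset correlation, 1 point per gene, red where the gene's own adjusted p is under 0.05 and grey otherwise, with a black line at the list's median. List medians run from -0.40 for mitochondrially encoded mRNAs to 0.36 for mesenchymal transition and invasion.

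Of the 38 lists tested, 4 were called higher and 8 lower. With an estimated correlation camera called 0 lists (smallest adjusted p = 0.503) and 2 had an unadjusted p under 0.05. The rotation test fry, which asks whether a list's genes move one way on balance, called 2 lists, p53 targets and cholesterol synthesis (adjusted p 0.0175 for both). All 12 called lists kept their direction under every scaling and in each fit without a library. Log2 fold changes also followed the position of genes: across 11954 genes they correlated with the number of protein-coding genes within 1 Mb at Spearman's rho = 0.28. The median was -0.12 in the fifth of genes with the fewest neighbours, where 144 rose and 517 fell, and 0.18 in the fifth with the most, where 424 rose and 102 fell.

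**Figure D3:**
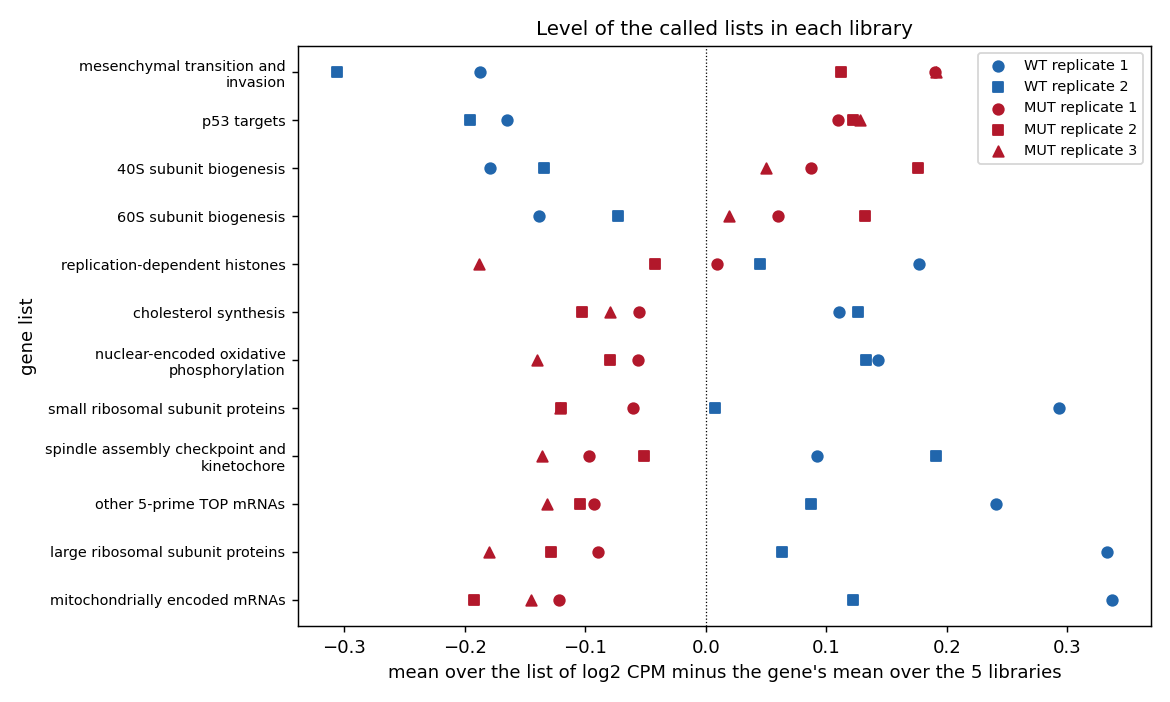
For each called list and library, the mean over the list's genes of log2 CPM minus the gene's mean over the 5 libraries, with blue points for WT and red points for MUT. WT and MUT libraries do not overlap in any of these lists. The lists were called for a difference between these same libraries, so this is not independent support. The gap was small for histones (0.045 in WT replicate 2 against 0.009 in MUT replicate 1). WT replicate 1 lies farther from the MUT libraries than WT replicate 2 for ribosomal protein (0.33 against 0.06 for the large subunit) and mitochondrially encoded mRNAs (0.34 against 0.12).

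Markers of other cell types were mostly too low to test. Of 17 fibroblast markers 6 were tested, of which ACTA2 rose and S100A4 fell (camera adjusted p 0.598). ACTA2 lost its call with DESeq2 (adjusted p 0.0719) and without WT replicate 1 (0.143) or MUT replicate 1 (0.054), and S100A4 in each fit without a library but the fit without MUT replicate 2 (0.0589 to 0.077). Of 17 blood and immune markers 5 were tested and 0 passed in edgeR, with CD68 at a log2 fold change of 1.14 and an adjusted p of 0.102. Of 21 markers of goblet, enteroendocrine and absorptive intestinal cells, 1 was tested, CA2, which rose 1.44-fold and lost its call without WT replicate 1 (adjusted p 0.0638). Of 16 neuronal and liver markers 4 were tested and 3 fell: TUBB3 went from 116 ± 7.38 to 53 ± 5.90 CPM, SYT1 fell 1.91-fold, and MAP2 had a log2 fold change of -0.76. MAP2 lost its call in 9 alternatives, among them DESeq2 (adjusted p 0.122), library size only (0.0562) and the fits without each library but MUT replicate 2 (0.0839 to 0.205). The last 2 lists had too few tested genes for camera with all libraries. Without WT replicate 1 or WT replicate 2 the neuronal and liver list had 5 tested genes, and camera called it lower (adjusted p 0.00677 and 0.0131).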

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

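Removing the gene density and span trend, thinning to the smallest library and leaving out Y-linked genes were chosen after seeing the data. The counts of genes called moved with the threshold, the test and the libraries used. Requiring a change of at least 2-fold left 144 higher and 81 lower genes, and DESeq2 called 609 higher and 948 lower, with 1553 genes shared with edgeR and 698 adjusted p values not given, while limma-voom called 1027 and 1528. Leaving out 1 library gave 509 to 1089 higher and 732 to 1339 lower genes, both lowest without WT replicate 2, which leaves 1 WT library that is assumed to vary like the MUT libraries. No gene called by edgeR was called in the opposite direction under any alternative. Library size only and upper-quartile scaling shared 2243 and 2412 of the 2747 calls, and removal of the density and span trend shared 1840. Of the 168 named genes past the threshold, 112 stayed past it in all alternative fits that gave them an adjusted p, 54 lost it in at least 1 fit without a library and 22 in another setting, most often (18) with the trend removed. None turned direction. Whether the WT and MUT replicate numbers mark pairs is open. Deviations of same-numbered libraries correlated at 0.079 and 0.15, over only 2 pairs. Both values rest on the same difference between the WT libraries, so they are not independent. WT replicate 1 and MUT replicate 3, numbered differently, gave 0.062. The replicate block gave 1529 higher and 1909 lower genes and 14 lists. For gene lists, 12 were called by camera, 12 to 16 without 1 library, 0 with an estimated correlation and 2 by fry. Fry asks a different question. The camera run with an estimated correlation used the same fit with only that setting changed, so the 12 calls depend on the preset correlation of 0.01. What in that setting removed them was not tested further. The lists that lost their call without a library were small-subunit proteins and 60S assembly (WT replicate 1), and cholesterol synthesis and mesenchymal genes (WT replicate 2). Cholesterol synthesis also lost it with the trend removed (adjusted p 0.0511, median -0.16). Shares of counts depended on the WT libraries: without 1 library the difference ran from -0.31 to -0.128 points for mitochondrially encoded mRNAs, -0.776 to -0.168 for ribosomal proteins, -0.28 to -0.0591 for histones, and -0.65 to 0.0783 for the 50 most abundant genes (5.77% in WT, 5.48% in MUT, exact permutation p 0.6).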

Other observations

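The tests of the Y chromosome as a whole, of equal falls of its genes and of its X-linked pairs, the trend removal, and the choice of Y-linked and zinc finger genes followed a look at the results. So did the use of bootstrap SEs in judging the list shifts, which made that rule stricter. In stress and signalling groups single genes moved in both directions, and camera called none of the lists in this paragraph and the next in the edgeR fit behind the report's values. Without WT replicate 1 it called aminoacyl-tRNA synthetases (0.0219) and cytosolic chaperones (0.0148) lower, as it did without MUT replicate 2 (0.0477 and 0.0286). It called the proteasome higher without WT replicate 2 (0.0178), with library size only (0.0389) and with the replicate block (0.0376), and redox genes lower without WT replicate 2 (0.0331). Of 31 genes of the integrated stress response (the ATF4 pathway) 3 rose and 7 fell, also adjusted over the list alone (adjusted p 0.424). The transcription factors ATF5 and ATF3 rose (log2 fold changes 1.02 and 0.75), while the amino acid enzyme ASNS, the transporter SLC38A2 and the folate enzyme MTHFD2 fell (-0.82, -0.50 and -0.46). Of 23 aminoacyl-tRNA synthetase genes 1 rose (FARSA) and 5 fell, or 1 and 6 adjusted over the list alone (0.125). FARSA lost its call without WT replicate 2 (0.0886) and with the density and span trend removed (0.0597). Of 30 genes listed for cytosolic chaperones and the heat shock response 10 fell and 1 rose, or 10 and 2 adjusted over the list alone (0.0817). The riser was HSF1, the regulator of the heat shock response, while HSPE1 and TCP1 fell. Of 26 ER chaperone and unfolded protein response genes 2 rose (P4HB and SEC61A1) and 3 fell, also adjusted over the list alone (0.743). P4HB lost its call with that trend removed (0.0583) and SEC61A1 without WT replicate 1 (0.0659). Proteasome genes included 8 that rose, led by PSMC4 (0.66), and 4 that fell among 34, also adjusted over the list alone (0.125). The 4 that fell, PSMD1, PSMA2, PSMA3 and PSMA4, were named after their values were seen. Of 31 genes of ribosome quality control 5 rose, among them the ribosome rescue factor PELO (0.60) and GCN1 (0.55), and 3 fell, also adjusted over the list alone (0.218).

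Glycolysis genes had 5 rises and 1 fall among 29, also adjusted over the list alone (adjusted p 0.187), with HK1 at 0.55 and LDHB at -0.47. Of 33 lysosome and autophagy genes 6 rose and 3 fell, also adjusted over the list alone (0.37), with the autophagy proteins GABARAPL2 and MAP1LC3B at -0.59 and -0.52. Of 27 redox genes 5 rose and 9 fell, or 5 and 10 adjusted over the list alone (0.255), with NQO1 at -0.43 and HMOX1 at 0.62. Of 21 interferon response genes 4 rose and 2 fell, also adjusted over the list alone (0.424). The antigen presentation genes parted, with B2M and PSMB9 at -0.72 and -1.51, and HLA-C, which has near-identical relatives, at 0.72. Of 16 NF-kB and inflammatory genes 4 rose and 2 fell, or 5 and 2 adjusted over the list alone (0.278), with CXCL8 at 1.77 and IL32 at -3.96. CXCL8 lost its call without WT replicate 2 (0.256), as did HMOX1 (0.102), MAP1LC3B (0.0504) and FOSL1 (0.0553). Of 27 MYC-related genes 5 rose and 6 fell, or 5 and 7 adjusted over the list alone (0.522), with the purine enzyme PAICS at -0.56. Of 26 MAPK feedback and immediate early genes 3 rose and 2 fell, or 4 and 4 adjusted over the list alone (0.636), with FOSL1 at 0.53. Of 20 hypoxia response genes 2 rose and 3 fell, or 3 and 3 adjusted over the list alone (0.987). Their median was -0.14, their mean 0.06 and the test's direction up. Counts of these lists often moved more than 1.5-fold without 1 library or with another scaling: without WT replicate 2, for example, 0 aminoacyl-tRNA synthetase genes fell, 0 redox genes rose and 1 lysosome gene rose.

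Genes on the Y chromosome, which HCT116 cells carry, were lower in MUT: all 8 tested were lower and 5 passed (RPS4Y1, DDX3Y, EIF1AY, USP9Y and UTY), with a median log2 fold change of -1.73, where the lowest of 10000 random lists matched on expression was -0.675. ZFY, KDM5D and TBL1Y did not pass and fell least, with log2 fold changes of -0.57, -0.75 and -0.79. The X-linked paralogs showed no gain to match the reads lost on Y: their sum changed by -108 CPM, against 144.7 CPM lost. Pair by pair this was clear only for RPS4Y1 and EIF1AY. The paralogs of the other 6 gained 29.1 CPM (SE 40.9) against 46.9 lost. This comparison takes the paralogs to be level otherwise, which is not known. RPS4X, the paralog of RPS4Y1, changed by -92.1 CPM (SE 52.2), but small-subunit protein genes fell as a list (median log2 fold change -0.25). A fall of its own could hide a gain of reads from Y, so reads moved to X-linked paralogs are not excluded. The falls differed by more than their SEs, also without RPS4Y1 (Cochran's Q of 27.3 over 7 genes, where SEs alone give 6 on average), which argues against 1 equal loss of Y unless reads of X-linked paralogs were counted to Y, and that was not tested. A loss or silencing of Y could lower all 8, and a move of reads to X was not excluded. Which of these it was, and whether it came with the eIF6 change or with the clone or culture used, stays open.

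The called gene lists were weighed against a trend with gene position and against WT replicate 1. After the trend with gene density and span was removed in each library (rho from 0.28 to 0.018), the 8 lower lists kept a median of 92.8% of their shift (bootstrap SE 9.8) and 7 kept their call. These include the mitochondrially encoded list, whose genes had no density value and got no correction, so its 100% was fixed in advance. The 4 higher lists kept 114% (SE 21) and 4 kept their call. Other TOP mRNAs kept 67.4%, cholesterol synthesis 68.6%, kinetochore genes 68.9% and mesenchymal genes 74%, so part of their shifts went with the trend. Large-subunit proteins kept 102% and 60S assembly 165%. These shares argue against that trend as the whole cause of either set, apart from the mitochondrially encoded list, for which it was not tested. Without WT replicate 1 the lower lists kept 73.3% (SE 7.7) and the higher lists 79.3% (SE 18), so part of their size may rest on that library. All these SEs come from resampling the lists, so they cover the spread between lists and not between libraries. Base composition itself stays open, as no sequence was used and MNase prefers A and T, and so does the difference between edited and unedited cells.

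Zinc finger genes (symbols starting ZNF, ZFP, ZSCAN or ZKSCAN and a digit, a family of mostly DNA-binding repressors) were lower in MUT. Of 412 tested 88 fell and 15 rose, with a median of -0.16. Of 10000 random lists matched on expression 0 had a median as low, so under 0.01% did, which argues against low counts as the reason. With the density and span trend removed 118% of the shift remained (SE 14, from resampling the family's genes). Chromosome 19 held 164 of the family, and all its tested genes had a median of 0.196, so removing the trend there could hardly shrink a fall. There the family's median went from -0.217 to -0.334, and on other chromosomes from -0.091 to -0.106. Before the removal, the median of -0.09 on other chromosomes lay below 95% of matched random lists (lower bound -0.006). The family's camera p was 0.000621, and p = 0.113 with an estimated correlation. A shared response of this family in MUT cells is a hypothesis that stays open beside base composition and other sequence features the repeats share, which were not tested.

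Some genes outside the naming rule, chosen after their values were seen, had larger changes at low counts. SLC40A1, the iron exporter ferroportin, had 12 and 15 counts in WT and 0 in all MUT libraries, at least 19.3-fold lower against a floor of 3 counts over the group. ZFP30 had 42 and 63 counts in WT and 2, 1 and 1 in MUT, and NRP1, a semaphorin and VEGF receptor, had 3 and 3 in WT and 37, 25 and 42 in MUT. WDR74, a 60S assembly gene whose span holds a U2 spliceosomal RNA gene, had 2347 to 3632 counts per library and a log2 fold change of -0.42 (adjusted p 0.0619).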
